A study of Mus musculus and Homo sapiens with 47 samples.

How the data were processed

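Bulk RNA-seq counts per gene of sorted mouse intestinal stem cells (8 libraries) and of the human lymphoma line SUDHL10 (13 libraries), and 3 droplet-based single-cell matrices of mouse intestinal stem cells, were used. Per the labels' protocols, the mice carried floxed Eed and an inducible Cre with GFP at Lgr5, received tamoxifen on 5 consecutive days and then on alternate days, and their GFP-positive cells were sorted after EDTA and enzyme treatment of the proximal intestine. The labels of SUDHL10 and of day 14 replicate 2 name a TruSeq V2 single-end library; those of the other bulk mouse libraries do not state the kit. The chromatin samples of the series were not analysed here.

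The bulk tables hold whole-number counts per gene as deposited, not normalized. Per the submitters' processing notes, STAR 2.5.3a, Bowtie2 2.3.4.3, SICER 0.0.1, DESeq2 (no version given) and Cell Ranger 3.0.2 were used and the build mm9 is named. Which tool made which file, the gene counter, the annotation and the human build are not given in the sources used here. The single-cell files hold UMI counts per gene and barcode as deposited, for all barcodes. Of the 24014 mouse genes, 27 carry a spreadsheet date in place of a symbol and are not named, and the human table has 25369 genes. 1 per-sample column of the mouse table, whose header names a day that no sample has, matched no sample and was not used. A second day 30 sample, which no column name matches, was not analysed here, so day 30 rests on 1 library. The 2 untreated SUDHL10 columns share a single header, so they served as replicates of their group without numbers. Totals were 21328684 to 27900351 counts per mouse library and 26234896 to 39315662 counts per human library. Replicates differed by more than counting noise: the lowest chi-square per degree of freedom of a pair, over genes with a summed count of at least 20, was 5.78, so no library was counted as a repeat of another.

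Each organism was fitted with 1 model over all its libraries, with a mean per group (day, or compound and day), in edgeR 4.0.16 under R 4.3.3: expression filter (filterByExpr), TMM scaling, quasi-likelihood F test and Benjamini-Hochberg adjustment over all tested genes, at an adjusted p threshold of 0.05. Groups of 1 library (day 30 and each MAK683 day) were tested with the spread of the other groups, and are assumed to vary like them. Residual degrees of freedom were 4 in mouse and 5 in human, prior degrees of freedom 4.56 and 18.6, and the common biological coefficient of variation 0.17 and 0.093. Standard errors of log2 fold changes were computed as the size of the fold change divided by the square root of F. CPM values use TMM effective library sizes, and a ± value is an SD over libraries. Of a gene with 0 counts in a whole group a bound is given, computed against 3 counts over that group. With 1 to 3 counts the ratio of counts is given with its exact 95% interval. Intervals and floors cover counting error only.

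For gene groups, 17 mouse and 17 human lists were written before the data were examined and tested with camera in limma 3.58.1 (preset correlation 0.01, two-sided, adjusted over all lists and comparisons of an organism). The adjustment was made separately for the comparisons fixed beforehand and for those added later. Each list was also tested with an estimated correlation. A list's median is also given with genes at 0 in a group set to their bounds, where this differs. The genes named in the text were fixed beforehand by rule: the targeted genes and Cdkn2a or CDKN2A; the 10 largest rises and 10 largest falls in 5 comparisons among called genes with mean log2 CPM of at least 1 and group ranges that do not overlap, leaving out clone identifiers; up to 4 members per list with the smallest adjusted p; and in single cells the 10 largest folds per direction. The second part was applied to day 21 against day 9 only after the data were seen. Genes named by the rule in 1 comparison are in places given in others too, single cells included, and these repeats were chosen after their values were seen. Symbols are those of the files, and no coordinates are printed. Some genes that the rule names are not reported here.

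Single cells were handled in Python 3.11.15 with scanpy 1.11.5, anndata 0.12.19 and SciPy 1.17.1. Barcodes were kept above 10% of the 99th percentile of UMIs among the 5000 largest (thresholds of 2532, 2179 and 2812 UMIs at days 7, 12 and 16), with at least 500 genes and at most 20% mitochondrial UMIs, which left 3828 of 4032, 4685 of 4894 and 2768 of 3134 barcodes. The doublet caller Scrublet marked 0.00886% of 11281 cells, so it did not work and doublets stayed in. UMIs were summed over the cells of a library and given with exact Poisson intervals, and shares of cells with exact Clopper-Pearson intervals. For shares, cells were thinned to 2000 UMIs. Cells were clustered by the Leiden method, and clusters were called X-like from markers fixed beforehand. The thresholds of that naming were set after the data were seen.

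The procedure was tested on simulated data with 200 genes changed by known folds. For day 21 against day 9, 65 of 66 genes changed 4-fold, 57 of 67 changed 2-fold and 23 of 67 changed 1.5-fold were recovered, with 10 unchanged genes called of 14214 tested. For day 30 against day 9 the same counts were 65, 46 and 7, with 12 unchanged genes called of 14206. For UNC1999 at day 5 against untreated they were 66 of 66, 66 of 67 and 57 of 67, with 8 called of 14449. The single-cell size rule recovered 200 of 200 genes changed 4-fold between days 7 and 16, with counting noise only. In both tests the changed genes lay above a lower limit of CPM, so recovery of genes near the floor was not tested.

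The alternatives fixed beforehand were DESeq2 1.42.0, DESeq2's size factors (RLE), no expression filter, the replicate number as a block, only the groups compared, and each replicate left out. For single cells they were other UMI, mitochondrial and thinning limits, and a count without mitochondrial and ribosomal genes. Lists were also tested with the block, and overlaps were recomputed over genes with mean log2 CPM of at least 3. Added after the data were seen were fits without day 14, UNC1999 against MAK683 by day, over days 1 and 3 only and as a difference between days, other days against day 1, raised genes under 1 CPM at day 9, an untreated library of its own for each compound, and counts without genes near 0 in a pair of days.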

Results

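Expression was measured in 2 systems in which Polycomb repressive complex 2 (PRC2) was targeted, the complex that methylates histone H3 to give the silencing mark H3K27me3. The first was the mouse intestinal stem cell. Mice with floxed alleles of Eed, a core PRC2 subunit, carried a tamoxifen-inducible Cre and GFP at the stem cell gene Lgr5, and GFP-positive cells were sorted from the proximal intestine. Bulk RNA was counted in 8 libraries, 3 of labelled day 9, 2 of day 14, 2 of day 21 and 1 of day 30 (a second day 30 sample was not analysed here), with 21328684 to 27900351 counts each. Droplet-based 3' single-cell RNA was counted in 1 library each of days 7, 12 and 16. The labels do not state the event from which days run, and no wild-type bulk RNA library was analysed here, so day 9 was the reference. The second system was SUDHL10, a human B cell lymphoma line treated at 5 uM with UNC1999, an inhibitor of the methyltransferases EZH2 and EZH1, or with MAK683, which binds EED. Its 13 libraries held 26234896 to 39315662 counts: 2 untreated libraries of day 5, 2 of UNC1999 at each of days 1, 3, 5 and 6, and 1 of MAK683 at each of days 1, 3 and 5. Where a single pair of counts is given for a gene list, the counts adjusted over the list alone were the same. Adjusted p-values are from edgeR's quasi-likelihood test unless another test is named. The labels call the libraries biological replicates without naming separate animals or cultures, so p-values measure the spread between these libraries, which may be partly technical.

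Eed RNA was counted in every mouse library. Its level was 46.1, 39.6 and 46.3 CPM (counts scaled to library size) in day 9 replicates 1 to 3, 86.1 and 81.5 CPM at day 14, 34.2 and 38.7 CPM at day 21 and 38.2 CPM at day 30. RNA from outside the deleted exons is still counted, so these levels check neither the deletion nor the labels. Eed was 1.91-fold higher at day 14 than at day 9 (adjusted p = 0.000106). The differences at day 21 (log2 -0.27, SE 0.11, adjusted p = 0.107) and day 30 (log2 -0.2, SE 0.13, adjusted p = 0.381) did not pass the test. Eed UMIs were found at days 7, 12 and 16 in 9.3%, 4.35% and 4.88% of single cells thinned to 2000 UMIs, with 1 library per day. Ezh2, the main catalytic subunit, lay between 92.6 and 121 CPM in the 8 libraries, and its paralogue Ezh1 between 50.7 and 70.4 CPM.

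By day 21 the stem cell libraries carried transcripts of a cell cycle inhibitor and of developmental regulators that had been near the floor at day 9. Cdkn2a, which encodes a CDK inhibitor and the ARF activator of p53, was at 0.387, 0.284 and 0.29 CPM in the day 9 libraries and at 11.9 and 11.6 CPM in those of day 21, a 36-fold rise (log2 5.17, SE 0.38, adjusted p = 3.57e-05). The single day 30 library, whose spread is taken from the other days, held 8.08 CPM, 24.8-fold over day 9 (adjusted p = 0.000236). The neighbouring inhibitor Cdkn2b rose from 9.13 CPM ± 1.55 (SD, n = 3) to 27.6 ± 1.02 (SD, n = 2) at day 21. In all, 4 of 7 CDK inhibitors were called higher at day 21, Cdkn1c (log2 0.97) and Cdkn2c (log2 0.85) being the others, and none lower, against 4 higher and 1 lower when adjusted over the list alone. The list's median log2 change was 0.85 (camera adjusted p = 0.00463, and adjusted p = 0.425 with an estimated correlation). At day 30, 1 of the 7 was called over all genes and 2 adjusted over the list alone (median 0.37, camera adjusted p = 0.066).

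Many Hox genes, which set position along the body axis, were called higher at the late days. At day 21, 20 of 30 measured Hox genes were called higher and 0 lower, 22 and 0 when adjusted over the list alone, with a median log2 change of 3.38 (3.34 with genes at 0 set to their bounds). At day 30, 16 were higher and 0 lower, 25 and 0 over the list alone, with a median of 4.24 (3.77 with bounds). Hoxb13, the most posterior gene of its cluster, went from 0.111 CPM ± 0.152 (SD, n = 3) at day 9 to 7.4 ± 1.57 (SD, n = 2) at day 21, 61.4-fold, and to 10.7 CPM at day 30, 88.4-fold. Hoxb6, Hoxa9 and Hoxd4 were at 2.56, 3.27 and 2.64 CPM at day 21 against 0.248, 0.57 and 0.099 CPM at day 9. Other developmental transcription factors moved the same way: 35 of 81 were called higher and 0 lower at day 21 (51 and 0 adjusted over the list alone, median 2.74, 2.62 with bounds), and 30 and 0 at day 30 (50 and 0 over the list alone, median 2.91, 2.85 with bounds). Barx1, a homeobox gene of stomach mesenchyme, rose 15-fold at day 21 and 26.6-fold at day 30, and Tbx15 25.7-fold at day 21. Sim2 had 2 counts at day 9 and 177 at day 21, a ratio of 103 with a 95% counting interval of 28.2 to 861. Foxc1 rose 20.9-fold at day 30. In the same comparisons 2 of 12 stromal and endothelial markers rose at day 21 (median 1.36, camera adjusted p = 0.0294, and adjusted p = 0.783 with an estimated correlation), and at day 30 their median was 0.36 (0.34 with bounds, camera adjusted p = 0.157). At day 21 the collagen gene Col1a2 had 102 counts against 1 (ratio 119, 95% counting interval 20.9 to 4760) and Col3a1 74 against 0, at least 28.8-fold higher. For the Hox list camera gave adjusted p = 1.52e-11 at day 21 and 6.92e-18 at day 30, and adjusted p = 0.477 and 0.425 with an estimated correlation. For the other factors it gave adjusted p = 8.79e-16 and 2.43e-22, and adjusted p = 0.186 at both days with an estimated correlation.

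**Figure D1:**
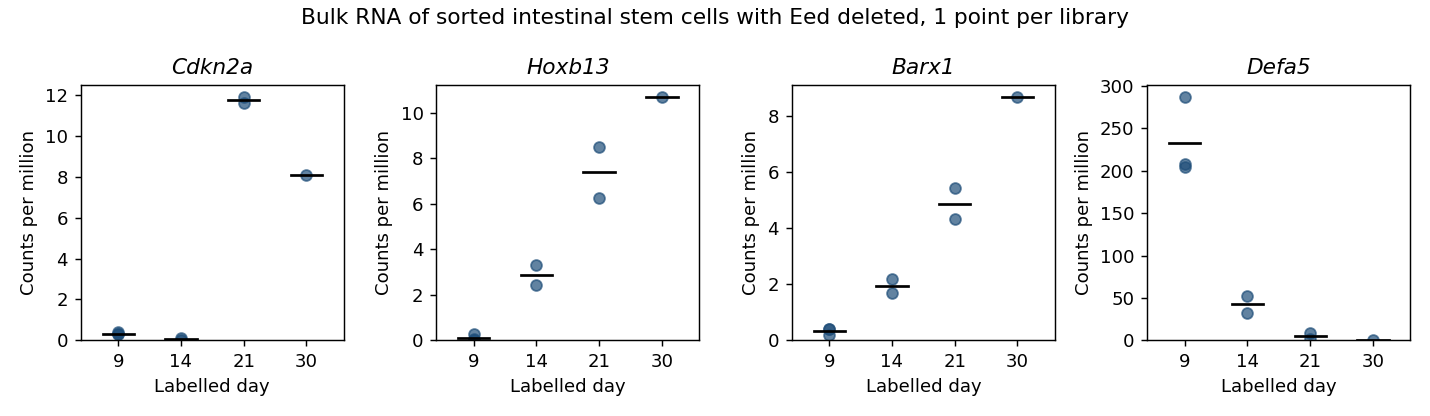
Level in CPM of Cdkn2a, Hoxb13, Barx1 and Defa5 in each bulk stem cell library (points) by labelled day, with the mean of each day as a bar. Cdkn2a stood at 11.9 and 11.6 CPM at day 21 and at 0.093 and 0 CPM at day 14, while Defa5 went from 205 CPM or more in each day 9 library to 0.464 CPM at day 30.

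Markers of differentiated cell types shifted within the sorted libraries. Tuft cell markers rose: 11 of 19 were called higher and 0 lower at day 21 (18 and 0 adjusted over the list alone, median log2 1.79, camera adjusted p = 4.72e-06, and adjusted p = 0.88 with an estimated correlation), and 9 and 0 at day 30 (17 and 0 over the list alone, median 1.92, camera adjusted p = 3.49e-09, and adjusted p = 0.783 with an estimated correlation). Dclk1, a tuft cell kinase, was at 68.1 CPM at day 30 against 10.5 ± 5.63 (SD, n = 3) at day 9. Of 17 Paneth cell markers, 3 were called lower and 0 higher at day 21 (median -0.76, camera adjusted p = 0.0202, and adjusted p = 0.88 with an estimated correlation) and 8 at day 30 (17 adjusted over the list alone, median -3.58, camera adjusted p = 1.7e-09, and adjusted p = 0.783 with an estimated correlation). Defa5, a defensin, was at 233 CPM ± 46.9 (SD, n = 3) at day 9, 4.85 ± 5.19 (SD, n = 2) at day 21 and 0.464 at day 30. Defensin genes are near-identical copies among which counting could split reads, so single members are uncertain. Enteroendocrine markers had 6 of 28 higher and 0 lower at day 21 (median 0.71, camera adjusted p = 0.00158, and adjusted p = 0.88 with an estimated correlation), among them the hormone genes Sst (76.8 against 16.9 CPM) and Gip (152 against 48.4 CPM). At day 30 they had 2 higher and 1 lower, Chga falling from 94.2 to 36.2 CPM. Goblet cell markers had 4 of 15 higher and 0 lower at day 21 (5 and 2 adjusted over the list alone) and 2 higher at day 30, the mucin gene Muc2 rising by 0.8 on the log2 scale at day 21. Enterocyte markers had 2 of 25 higher at day 21 (median 0.88, camera adjusted p = 0.014, and adjusted p = 0.889 with an estimated correlation) and 4 lower at day 30 (17 lower adjusted over the list alone, median -1.73, camera adjusted p = 3.2e-06, and adjusted p = 0.88 with an estimated correlation). Alpi, the intestinal alkaline phosphatase, went from 88.2 CPM at day 9 to 265 ± 182 (SD, n = 2) at day 21 and 22.2 CPM at day 30.

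Among stem cell markers, some members fell at day 21 and others rose at day 30. At day 21, 10 of 25 were called lower and 0 higher, 14 and 1 adjusted over the list alone, with a median of -0.28 that did not pass (camera adjusted p = 0.0697). Lgr5 was at 169 CPM ± 17.2 (SD, n = 3) at day 9, 120 ± 0.252 (SD, n = 2) at day 21 and 176 CPM at day 30. Olfm4 was at 7400 ± 733 (SD, n = 3), 4780 ± 7.59 (SD, n = 2) and 8140 CPM. At day 30, 3 markers were higher and 0 lower (4 and 0 adjusted over the list alone), among them the RNA-binding protein gene Msi1 (76.3 against 40.2 CPM). Of 20 immediate-early and heat-shock genes, 7 fell and 0 rose at day 21 (13 adjusted over the list alone, median -0.6, camera adjusted p = 0.0444, and adjusted p = 0.88 with an estimated correlation) and 3 at day 30 (11 over the list alone, median -0.81, camera adjusted p = 0.000558, and adjusted p = 0.88 with an estimated correlation). Fos fell from 1070 to 484 CPM and Atf3 from 410 to 104 CPM at day 30. Cell cycle genes had 6 of 43 higher and 3 lower at day 21 (median 0.1, camera adjusted p = 0.151), Plk1 being higher (142 against 73.4 CPM) and Pcna lower (144 ± 4.95, SD, n = 2, against 312 ± 38.8, SD, n = 3). At day 30 their median of 0.21 passed (camera adjusted p = 0.00847, and adjusted p = 0.889 with an estimated correlation). PRC2 subunits had 2 of 12 higher and 1 lower at day 21, and PRC1 subunits 3 of 20 higher and 6 lower (3 and 7 adjusted over the list alone). Rybp, a PRC1 subunit, fell from 72.6 to 19.7 CPM at day 21 and to 20.1 CPM at day 30, and Kdm2b from 94.2 to 41.5 CPM at day 21. Of 20 p53 targets, 3 were higher and 4 lower at day 21 (3 and 5 adjusted over the list alone), Trp53inp1 falling by 2.21 on the log2 scale. Of 26 immune markers 3 rose at low levels at day 21 (Csf1r, C1qb and Lyz2, with 2 adjusted over the list alone, median 0.32, camera adjusted p = 0.0709). Csf1r had 67 counts against 2 (ratio 39.2, 95% counting interval 10.4 to 330).

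Over 14692 tested genes, day 21 differed from day 9 at 2974 (1096 higher and 1878 lower) and day 30 at 1511 (539 and 972). Of these, 448 were higher and 840 lower at both days. Igf2, an imprinted growth factor gene, rose 6.47-fold at day 21 (adjusted p = 1.49e-05) and 5.98-fold at day 30, Igf2bp3 5.43-fold at day 30, and the imprinted gene Grb10 from 1.64 CPM to 9.28 and 12.1 CPM. Mptx1, a pentraxin gene of Paneth cells, rose from 58.1 CPM ± 16.1 (SD, n = 3) to 504 ± 62.7 (SD, n = 2) at day 21. Several of the largest falls were genes read at 10 CPM or more in every day 9 library and under 1 CPM in every library of days 21 and 30. There were 19 such genes, including Sumo2, which went from 186 CPM to 0.223 and 0.298 CPM but stood at 489, 597 and 393 CPM in the single cells of days 7, 12 and 16. Xist, expressed from the inactive X chromosome, was at 711 to 1260 CPM in the day 9 libraries, 0.511 and 0 at day 14, 815 and 3.09 at day 21 and 1.32 at day 30, and the Y-linked Eif2s3y was at 0 at day 9, 47.3 and 55.4 CPM at day 14, 0.0355 and 39.6 CPM at day 21 and 53.6 CPM at day 30. By these genes, days 14 and 30 against day 9 also compare male with female libraries, and day 21 was mixed, so sex and day cannot be told apart there. With library-size scaling in place of TMM the median gene shifted by 0.22 at day 21 and 0.21 at day 30 against day 9, and by 0.18 between days 14 and 21, on the log2 scale, and changes are given on the TMM scale. The counts fell to 1864 at day 21 and 875 at day 30 without day 9 replicate 1, and to 1944 or 1962 at day 21 without replicate 1 or 2 of that day.

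In Cdkn2a and other genes day 14 did not lie between days 9 and 21. Cdkn2a had 2 counts and 0 counts in its libraries (ratio to day 9 of 0.148, 95% counting interval 0.0169 to 0.602). Hoxb13 was already 23.8-fold higher than at day 9, at 2.86 CPM ± 0.616 (SD, n = 2), and Tbx15 was higher by 3.42 on the log2 scale, but 6 Hox genes of 30 were higher and 2 lower (2 and 0 adjusted over the list alone) and 15 other developmental factors of 81 higher and 5 lower (14 and 5 over the list alone). Neither list passed (camera adjusted p = 0.316 and 0.236). Cell cycle genes rose, 25 of 43 against 2 lower (28 and 2 adjusted over the list alone, median 0.47, camera adjusted p = 9.51e-05, and adjusted p = 0.88 with an estimated correlation). Birc5, a mitotic regulator, was at 196 against 74.3 CPM and the ribonucleotide reductase subunit Rrm2 at 180 against 63.5 CPM. The CDK inhibitor Cdkn1b fell from 85.1 to 13 CPM. Enterocyte markers fell, 13 of 25 and 0 higher (median -1.52, camera adjusted p = 0.0202, and adjusted p = 0.889 with an estimated correlation), the aminopeptidase gene Anpep going from 624 to 90.8 CPM. Of 25 stem cell markers 6 were higher and 14 lower (6 and 15 adjusted over the list alone). Sox9 rose from 165 to 355 CPM, whereas the Wnt target Axin2 fell from 426 to 97.5 CPM and Msi1 from 40.2 to 1.78 CPM. Immediate-early genes had 3 of 20 higher and 10 lower (3 and 11 adjusted over the list alone, median -0.55, camera adjusted p = 0.0534), Fosb falling from 331 to 26.4 CPM. Stromal and endothelial markers had 0 of 12 higher and 4 lower (0 and 2 adjusted over the list alone, median -2.04, -1.3 with bounds, camera adjusted p = 0.391). Immune markers had 0 of 26 higher and 6 lower (0 and 5 over the list alone, median -1.65, -1.58 with bounds, camera adjusted p = 0.257). In total 7508 genes were called, 3734 higher and 3774 lower, with 793 at least 2-fold higher and 2176 at least 2-fold lower. Among the largest changes were rises of the linker histone gene Hist1h1b (26.3 CPM ± 3.04, SD, n = 2, against 0.893 ± 0.178, SD, n = 3) and Apobec3 (143 against 20.5 CPM), and falls of the transcription factor gene Foxo4 (1.62 against 78.8 CPM, 48.6-fold) and Tatdn2 (51.2-fold). The day 14 libraries had counts in 14988 and 13707 genes, against 16163 to 16952 in the others.

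From day 14 to day 21, 8609 genes were called (4328 higher and 4281 lower). Cdkn2a rose from 2 counts to 687 (ratio 247, 95% counting interval 68.1 to 2040), Eed fell 2.3-fold and Mki67, a proliferation marker, rose 4.13-fold, whereas 25 of 43 cell cycle genes fell and 4 rose (26 and 4 adjusted over the list alone, median -0.47, camera adjusted p = 0.0294, and adjusted p = 0.889 with an estimated correlation). Hox genes had 13 higher and 0 lower (median 2.17, camera adjusted p = 0.0294, and adjusted p = 0.88 with an estimated correlation), other developmental factors 34 and 2 (27 and 1 adjusted over the list alone, median 1.45, camera adjusted p = 0.00763, and adjusted p = 0.76 with an estimated correlation), and enterocyte markers 20 and 0 (median 2.13, camera adjusted p = 0.00248, and adjusted p = 0.88 with an estimated correlation). Markers of other cell types moved in the same comparison. Stromal and endothelial markers had 9 of 12 higher and 0 lower (median 4.29, 2.9 with bounds, camera adjusted p = 0.0884). Immune markers had 13 of 26 higher and 0 lower (12 and 0 adjusted over the list alone, median 2.43, camera adjusted p = 0.0781). Col1a2 had 102 counts against 0, at least 24.4-fold higher, and Csf1r 67 against 0, at least 16-fold. Enteroendocrine markers had 13 of 28 higher and 0 lower (median 1.05, camera adjusted p = 0.066). Goblet cell markers had 9 of 15 higher and 2 lower (median 0.73, camera adjusted p = 0.069). Tuft cell markers had 4 of 19 higher and 0 lower (1 and 0 over the list alone, median 0.92, camera adjusted p = 0.353). Paneth cell markers had 0 of 17 higher and 6 lower (0 and 3 over the list alone, median -1.21, camera adjusted p = 0.139).

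Between days 21 and 30 edgeR called 0 genes. There were 1218 genes at an unadjusted p under 0.05, DESeq2 called 299, edgeR without the expression filter called 36, and edgeR called 34 or 335 without day 21 replicate 1 or 2. Adjusted over the list alone, 24 of 25 enterocyte markers (median -2.74, camera adjusted p = 1.03e-42, and adjusted p = 0.425 with an estimated correlation) and 12 of 17 Paneth markers (median -2.9, camera adjusted p = 1.71e-15, and adjusted p = 0.644 with an estimated correlation) were lower, and 13 of 25 stem cell markers higher (median 0.37, camera adjusted p = 1.52e-15, and adjusted p = 0.331 with an estimated correlation). Immune markers had a median of -1.67 (camera adjusted p = 8.45e-08, and adjusted p = 0.643 with an estimated correlation). Enteroendocrine markers, 2 of 28 lower adjusted over the list alone, had a median of -0.45 (camera adjusted p = 8.65e-06, and adjusted p = 0.783 with an estimated correlation). The median of stromal and endothelial markers was -1.33 (camera adjusted p = 0.066). The Hox list had a median of 0.48 (camera adjusted p = 0.0388, and adjusted p = 0.88 with an estimated correlation). CDK inhibitors, 1 of 7 lower over the list alone, had a median of -0.54 (camera adjusted p = 0.0302, and adjusted p = 0.55 with an estimated correlation). Immediate-early and heat-shock genes had a median of -0.2 (camera adjusted p = 0.00961, and adjusted p = 0.88 with an estimated correlation).

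In single cells Cdkn2a and Hoxb13 stood higher at day 16 than at days 7 and 12. After filtering, 3828, 4685 and 2768 cells remained at days 7, 12 and 16, with medians of 7957, 7560 and 11905 UMIs per cell. With 1 library per day there is no test, and intervals cover counting error only. Cdkn2a had 0 of 35504044 UMIs at day 7 (floor of 0.084 CPM), 51 at day 12 (1.26 CPM) and 944 at day 16 (26.8 CPM, 95% interval 25.1 to 28.5). Thinned to 2000 UMIs per cell, 0.171% of day 12 cells (0.0737 to 0.336) and 4.3% of day 16 cells (3.57 to 5.12) had a Cdkn2a UMI, against 0.619% and 13.4% before thinning. Free RNA can contribute to such shares. Barcodes too low in UMIs to count as cells held 24.8 CPM of Cdkn2a at day 16, and the immune-like cluster, median depth 3915 UMIs, held 1 UMI (8.72 CPM, 0.221 to 48.6). Hoxb13 had 0, 1 and 339 UMIs at the 3 days, Barx1 1, 12 and 327, Cdkn2b 30, 207 and 725, and Hoxb6 1, 1 and 58. Igf2 was already at 123 UMIs at day 12, against 3 at day 7 and 119 at day 16. Hox genes together took 0.00183%, 0.00178% and 0.00535% of UMIs. The other developmental transcription factors took 0.0536%, 0.063% and 0.0421%, so their share was lower at day 16 than at day 7.

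At day 16 the level of Cdkn2a differed between clusters. It was 128 CPM (117 to 140, 487 UMIs) in the larger enterocyte-like cluster, 47.8 CPM (40.5 to 56) in an unnamed cluster led by both Paneth and goblet cell genes, 17.8 CPM (9.47 to 30.4) in enteroendocrine-like cells and 16.1 CPM (13.8 to 18.6) in a cycling cluster. In the cluster of 1377 day 16 cells led by Olfm4 it was 6.68 CPM (5.45 to 8.11), and in tuft-like cells 5.56 CPM (1.15 to 16.2). A smaller enterocyte-like cluster, with 22 day 16 cells and all 25 enterocyte markers leading against 16 in the larger one, held 12.4 CPM (3.39 to 31.8, 4 UMIs). All these values except those of the larger enterocyte-like and the unnamed cluster lay below the day 16 level of the low-UMI barcodes given above. Free RNA may thus contribute to them, and they do not show expression in those cells. The interval of the larger enterocyte-like cluster lay above those of the other clusters named here, the smaller enterocyte-like cluster included. Most clusters held cells of mainly 1 library, so a cluster may be that library rather than a type, and cluster sizes are not compared.

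**Figure D2:**
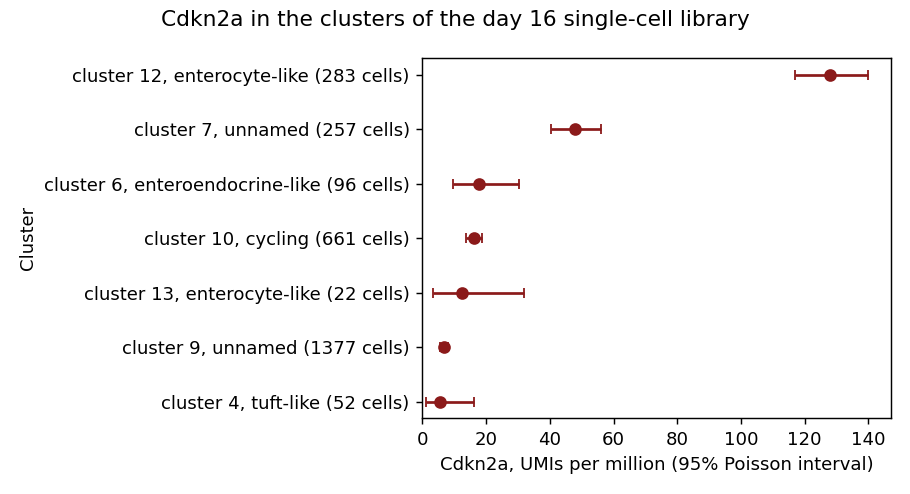
Level of Cdkn2a in CPM, from summed UMIs, in each cluster with at least 20 cells of day 16, with exact 95% Poisson intervals as bars. The larger enterocyte-like cluster stood highest, at 128 CPM, and the tuft-like cluster lowest, at 5.56 CPM. Levels below that of the low-UMI barcodes of the same library may come from free RNA.

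By the size rule (at least 2-fold, at least 20 CPM in the higher library, intervals apart), 315 genes were higher and 116 lower at day 12 than at day 7, and 305 higher and 389 lower at day 16. At day 12 the imprinted gene H19 stood at 69.9 against 2.56 CPM, the growth factor gene Mdk at 38.1 against 1.58 CPM and the pancreatic lipase-related gene Pnliprp1 at 228 against 12.3 CPM, while Olfm4 stood at 10.1 against 241 CPM. Both Olfm4 values are far below the 4770 to 8140 CPM of the bulk libraries. Whether the assay or the cells sampled differ was not tested, so these single-cell days may not belong to 1 series with bulk. At day 16 the incretin gene Gip stood at 313 against 0.366 CPM, Mptx1 at 1110 against 1.63 CPM and Car4 at 31.9 against 0.422 CPM, while Ifitm1 stood at 0.369 against 485 CPM and the Wnt inhibitor gene Notum at 0.539 against 88.9 CPM. Among members at 20 CPM or more, 16 of 23 stem cell markers were lower at day 16, and 10 of 14 enterocyte, 7 of 9 goblet and 10 of 10 enteroendocrine markers were higher. Of 17 Paneth markers 0 were higher and 7 lower, and of 6 immune markers 2 were higher and 3 lower. Lgr5 had 6982, 9406 and 1583 UMIs at the 3 days. Of cell cycle genes, 0 of 37 met the rule at day 16. Xist stood at 1300 CPM at day 7 and 0.851 CPM at day 16, and the Y-linked Ddx3y at 0 and 39.1 CPM. By these genes the 2 libraries also differed in sex, which cannot be told apart from day here. The 536 genes raised at least 2-fold at day 21 or 30 in bulk took 0.992%, 1.38% and 0.97% of UMIs, and 18 of them met the size rule as higher and 18 as lower at day 16. For the 284 of them under 1 CPM at day 9, a subset chosen after the data were seen, the direction from day 7 to day 16 was turned, with shares of 0.037% (0.0364 to 0.0377), 0.0684% and 0.0533% (0.0525 to 0.0541), and 3 met the size rule as higher and 2 as lower at day 16.

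In SUDHL10 transcripts of EED, EZH2, EZH1 and CDKN2A were counted in every library. EED was at 35 and 32.4 CPM in the untreated libraries, 51.2 and 54 CPM at day 1 of UNC1999, 40 and 40.8 at day 3, 34.9 and 38.2 at day 5 and 41.1 and 38.9 at day 6, and at 56.5, 46.6 and 33.2 CPM at days 1, 3 and 5 of MAK683. EZH2 lay between 180 and 259 CPM in all 13 libraries. EZH1 was at 97.7 and 77 CPM untreated, between 38.9 and 61.2 CPM under UNC1999, and at 49.5, 42.8 and 102 CPM at days 1, 3 and 5 of MAK683. CDKN2A was at 141 and 155 CPM untreated, 102 to 116 CPM under UNC1999, and 127, 95.4 and 152 CPM under MAK683. Both compounds act on the protein, so RNA levels do not check the treatment.

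Day 5 is the day at which treated and untreated libraries match. Against untreated cells, AGR2, ACE, PADI2 and EFR3B were among the genes that rose most after 5 days of UNC1999, and MT2A, MT1X, TP63 and BBC3 among those that fell most. AGR2, a secretory-pathway disulfide isomerase, went from 0.17 CPM ± 0.157 (SD, n = 2) to 108 ± 14.4 (SD, n = 2), 611-fold (adjusted p = 7.59e-20). ACE, the angiotensin-converting enzyme, rose 495-fold to 30.3 CPM, PADI2 134-fold to 106 CPM, and EFR3B 185-fold to 32.7 CPM. The metallothionein genes MT2A and MT1X fell from 877 to 8.68 CPM and from 637 to 22.1 CPM. These genes belong to a family of close copies, so their split is uncertain. TP63, a p53-family transcription factor, fell 51.7-fold and BBC3, which encodes the pro-apoptotic PUMA, 18.5-fold. In all, 8968 of 15278 genes were called, 4785 higher and 4183 lower, 2210 and 1474 of them by at least 2-fold.

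In UNC1999 at day 5, of 16 p53 targets, 10 were lower and 3 higher (median -1.07, camera adjusted p = 2.34e-05, and adjusted p = 0.222 with an estimated correlation), including FAS (6.7 against 52.3 CPM) and PMAIP1 (39 against 188 CPM). Of 25 ATF4 and unfolded-protein response genes, 17 were lower and 5 higher (median -1.23, camera adjusted p = 1.59e-05, and adjusted p = 0.297 with an estimated correlation). The amino acid response gene ASNS fell 3.44-fold while the endoplasmic reticulum chaperone genes HSPA5 and SDF2L1 rose 6.37-fold and 7.7-fold. Germinal centre genes had 13 of 24 lower and 4 higher (median -0.28, -0.29 with bounds, camera adjusted p = 0.000324, and adjusted p = 0.354 with an estimated correlation), MME falling from 265 to 118 CPM. BCL2 family genes had 8 of 15 lower and 5 higher (9 and 5 adjusted over the list alone, median -0.38, camera adjusted p = 0.016, and adjusted p = 0.455 with an estimated correlation), and CDK inhibitors 4 of 6 lower and 1 higher (4 and 2 over the list alone, median -1.16, camera adjusted p = 0.032, and adjusted p = 0.27 with an estimated correlation), CDKN1B falling 3.5-fold and CDKN2D 6.23-fold. CDKN2A fell by 0.51 on the log2 scale (SE 0.08, adjusted p = 5.18e-06), and EZH1 fell by 0.99 (SE 0.12). Plasma cell and memory B cell genes had 12 of 20 higher and 1 lower (median 0.9, camera adjusted p = 0.0673), CD44 rising from 0.807 to 15.2 CPM. HOX genes had 6 of 19 higher and 5 lower (median 0.2, camera adjusted p = 0.983), HOXA9 falling from 4.89 to 1.52 CPM and HOXA13 rising from 0.0589 to 2.71 CPM. Other developmental factors had 10 of 36 higher and 9 lower (9 and 9 adjusted over the list alone), SOX2 rising 93.1-fold to 5.71 CPM. Cell cycle genes had 18 of 43 higher and 17 lower, with the replication gene MCM5 at 375 against 121 CPM and UHRF1 at 174 against 37.3 CPM. Cholesterol synthesis and uptake genes had 12 of 24 higher and 8 lower (median 0.19, camera adjusted p = 0.379).

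The other UNC1999 days gave similar counts, 8354 genes at day 1, 8717 at day 3 and 8899 at day 6, against untreated libraries of day 5. At day 1, cholesterol synthesis genes were higher, 18 of 24 and 2 lower (median 0.58, camera adjusted p = 2.27e-07, and adjusted p = 0.27 with an estimated correlation). Within UNC1999, free of the untreated libraries, 6349 genes differed between days 5 and 1 (2994 higher and 3355 lower), 1864 of them at least 2-fold higher and 273 at least 2-fold lower. Which direction held more calls turned with the setting: DESeq2's size factors gave 3300 higher and 2589 lower, DESeq2 3131 and 2427, no filter 3339 and 2415, the replicate block 3218 and 2961, and only the groups compared 3532 and 2875. It also turned without UNC1999 day 1 replicate 2 (2550 and 1824) and without day 5 replicate 1 (2344 and 2332). SOX2 went from 0 to 449 counts, at least 117-fold, and the lymphoid gene TCL1A from 0 to 231 counts, at least 60.1-fold. MHC genes had 15 of 26 higher and 1 lower (15 and 3 adjusted over the list alone, median 0.51, camera adjusted p = 1.39e-05, and adjusted p = 0.254 with an estimated correlation), HLA-DRA rising from 509 to 1070 CPM. Plasma cell and memory B cell genes had 11 of 20 higher and 3 lower (median 0.87, camera adjusted p = 0.00698, and adjusted p = 0.222 with an estimated correlation), CD44 rising 25.7-fold. The B cell surface gene MS4A1 rose from 320 to 1000 CPM. Cholesterol synthesis genes had 20 of 24 lower and 1 higher (median -0.51, camera adjusted p = 7.3e-08, and adjusted p = 0.27 with an estimated correlation). Of 8 markers of other blood cells, 3 rose from near the floor (median 3.87, 1.93 with bounds, camera adjusted p = 0.0442, and adjusted p = 0.27 with an estimated correlation), CSF1R from 3 counts to 183 (ratio 47.6, 95% counting interval 16 to 233).

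MAK683 at day 5, with 1 library whose spread is borrowed from the other groups, gave fewer calls: 4522 genes, 2372 higher and 2150 lower, 1088 and 339 of them by at least 2-fold. The direction with more calls turned with DESeq2's size factors (2136 higher and 2545 lower), DESeq2 (2004 and 2486), no filter (2265 and 2383), only the groups compared (2073 and 2076) and without untreated replicate A (1828 and 2458). AP1S3 rose 49.6-fold to 18 CPM (adjusted p = 5.74e-13), SCD5, a fatty acid desaturase gene, 30.7-fold, the transporter gene ABCB4 29.6-fold and ACE 27.7-fold. MT2A fell 325-fold and MT1X 135-fold. HOXB9 had 0 counts against 273, at least 37.9-fold lower. Cell cycle genes fell, 29 of 43 and 0 higher (32 and 0 adjusted over the list alone, median -0.43, camera adjusted p = 1.46e-12, and adjusted p = 0.222 with an estimated correlation), MCM4 going from 367 to 203 CPM and TK1 from 115 to 59.2 CPM. Cholesterol synthesis genes fell, 19 of 24 and 0 higher (20 and 0 adjusted over the list alone, median -0.63, camera adjusted p = 1.95e-15, and adjusted p = 0.222 with an estimated correlation), HMGCS1 going from 588 to 292 CPM. MHC genes rose, 17 of 26 against 1 lower (19 and 1 adjusted over the list alone, median 0.52, camera adjusted p = 7.3e-08, and adjusted p = 0.222 with an estimated correlation), HLA-B going from 1060 to 2390 CPM. PRC1 subunits had 10 of 20 higher and 2 lower (median 0.47, camera adjusted p = 0.000128, and adjusted p = 0.222 with an estimated correlation), among them BMI1 (26.3 against 8.47 CPM) and PCGF5 (126 against 48.2 CPM). B cell identity genes had 9 of 20 higher and 2 lower (9 and 3 adjusted over the list alone, median 0.22, camera adjusted p = 0.0115, and adjusted p = 0.231 with an estimated correlation), CD37 at 1770 against 732 CPM, and the anti-apoptotic gene BCL2 was at 34.5 against 6.95 CPM. EED, EZH2, EZH1 and CDKN2A differed from untreated by log2 -0.02, 0.24, 0.23 and 0.04, none past the test. Days 1 and 3 of MAK683 gave 7430 and 7392 genes. Cell cycle genes there had 21 higher and 11 lower at day 1 (22 and 11 adjusted over the list alone, median 0.22, camera adjusted p = 0.00232, and adjusted p = 0.442 with an estimated correlation). At day 3 they had 22 and 14 (22 and 15 over the list alone, median 0.39, camera adjusted p = 0.0681). MHC genes had 6 higher and 12 lower at day 1 (median -0.26, camera adjusted p = 0.129) and 4 and 7 at day 3 (median -0.01, camera adjusted p = 0.488). B cell identity genes had 6 higher and 8 lower at day 1 (median 0.03, 0.13 with bounds, mean -0.4, camera adjusted p = 0.304). At day 3 they had 2 and 11 (median -0.5, -0.54 with bounds, camera adjusted p = 0.00945, and adjusted p = 0.231 with an estimated correlation). PRC1 subunits had 6 higher and 7 lower at day 1 and 8 and 5 at day 3 (camera adjusted p = 0.694 and 0.983). At day 1 the list medians were -0.89 for cholesterol synthesis (camera adjusted p = 1.2e-09, and adjusted p = 0.245 with an estimated correlation), -1.47 for ATF4 and unfolded-protein response genes (adjusted p = 2.54e-08, and adjusted p = 0.254 with an estimated correlation) and -1.13 for p53 targets (adjusted p = 1.18e-05, and adjusted p = 0.222 with an estimated correlation).

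Set against each other at 5 uM over days 1, 3 and 5, the 2 compounds differed in cholesterol synthesis and uptake genes. Of 24 measured members, 23 were higher under UNC1999 than under MAK683 and 0 lower, with 24 and 0 adjusted over the list alone (median 0.96, camera adjusted p = 4.78e-77, and adjusted p = 0.0481 with an estimated correlation). HMGCS1, which makes HMG-CoA, was at 921 CPM ± 363 (SD, n = 6) against 273 ± 40.4 (SD, n = 3), a log2 difference of 1.68 (SE 0.055), and LSS was 3.3-fold higher. Taken day by day, comparisons added after the data were seen, 23 members were higher at day 1 (23 higher and 1 lower adjusted over the list alone, median 1.5, camera adjusted p = 2.25e-171, and adjusted p = 0.00603 with an estimated correlation), 23 at day 3 (median 0.72, camera adjusted p = 3.38e-27, and adjusted p = 0.157 with an estimated correlation) and 17 at day 5, with 2 lower (18 and 2 over the list alone, median 0.76, camera adjusted p = 4.36e-09, and adjusted p = 0.248 with an estimated correlation). Other named genes that were higher under UNC1999 were EFR3B (203-fold, 24.4 CPM ± 10.2, SD, n = 6, against 0.215 ± 0.293, SD, n = 3), the integrin gene ITGAD (82.7-fold), the germinal centre gene RGS13 (72.7 against 21.8 CPM) and PHF19, a PRC2-associated protein (174 against 115 CPM). AMPD3, an AMP deaminase gene, was 3.74-fold lower, and CD37 differed by log2 -1.06. ATF4 and unfolded-protein response genes had 12 of 25 higher and 3 lower (13 and 3 adjusted over the list alone, median 0.19, camera adjusted p = 0.0112, and adjusted p = 0.52 with an estimated correlation), and MHC genes 2 of 26 higher and 9 lower (median -0.06, camera adjusted p = 0.0265, and adjusted p = 0.442 with an estimated correlation). By day, the ATF4 list had 9 higher and 0 lower at day 1 (11 and 0 adjusted over the list alone, median 0.24, camera adjusted p = 1.47e-07, and adjusted p = 0.267 with an estimated correlation). At day 3 it had 18 and 2 (18 and 3 over the list alone, median 0.61, camera adjusted p = 2.85e-19, and adjusted p = 0.175 with an estimated correlation). At day 5 its direction was turned, with 5 higher and 15 lower (5 and 17 over the list alone, median -0.57, camera adjusted p = 0.000643, and adjusted p = 0.331 with an estimated correlation). MHC genes had 1 higher and 3 lower at day 1 (1 and 4 over the list alone, median -0.07, camera adjusted p = 0.164), 6 and 3 at day 3 (median 0.06, camera adjusted p = 0.513). At day 5 they had 5 and 13 (median -0.25, camera adjusted p = 0.00909, and adjusted p = 0.331 with an estimated correlation). Cell cycle genes had 15 of 43 higher and 16 lower over the 3 days (17 and 16 over the list alone, median 0.01, camera adjusted p = 0.129). At day 1 they had 1 higher and 24 lower (1 and 29 over the list alone, median -0.41, camera adjusted p = 1.28e-16, and adjusted p = 0.175 with an estimated correlation). At day 3 they had 4 and 6 (median 0.04, camera adjusted p = 0.938). At day 5 they had 22 and 9 (22 and 10 over the list alone, median 0.4, camera adjusted p = 1.85e-06, and adjusted p = 0.283 with an estimated correlation). EED (log2 -0.06, SE 0.069) and EZH2 (log2 -0.14, SE 0.06) did not pass the test. EZH1 (log2 -0.34, SE 0.083) and CDKN2A (log2 -0.18, SE 0.056) were lower, and over days 1 and 3 only, an alternative chosen after the data were seen, their log2 differences were 0.1 and 0.02. In total 5841 genes were called, 3012 higher and 2829 lower, and 2929 over days 1 and 3 only, 1389 higher and 1540 lower. A model of compound and day over the same libraries, in which differences of the compound effect between days add to the spread, called 162. By day the counts were 1230, 3455 and 7955. The day 1 count was 761 without UNC1999 day 1 replicate 1.

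**Figure D3:**
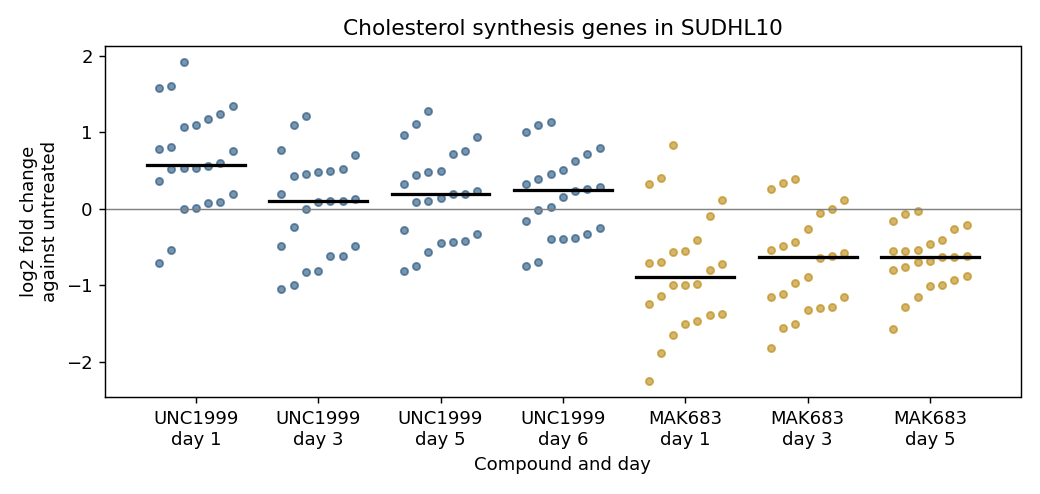
Log2 fold change against the untreated libraries of each of the 24 measured cholesterol synthesis and uptake genes (points), with the median as a bar, by compound and day. The medians were 0.58 at day 1 of UNC1999 and -0.89 and -0.63 at days 1 and 5 of MAK683.

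Changes against the shared untreated libraries were compared across genes, which are not independent replicates. The Pearson correlation of log2 fold changes between UNC1999 and MAK683 was 0.743 at day 1, 0.632 at day 3 and 0.345 at day 5, where unchanged groups simulated against the same controls gave 0.36, 0.383 and 0.366. The covariance was 2.29, 2.03 and 0.935, against 0.198, 0.198 and 0.192 simulated, so the differences were 2.09, 1.83 and 0.742. Genes higher under both compounds numbered 3503, 3222 and 1247, where independent lists of the same sizes would share 1130, 1206 and 743. Genes lower under both numbered 2877, 2680 and 807 against 907, 912 and 589, and genes called in opposite directions 74, 135 and 1366. The observed numbers share the untreated libraries, so part of the excess may come from them. Groups simulated as unchanged against the same controls had 0 genes called in the same direction under both compounds. Such groups hold no true changes, so this count cannot show how much shared controls add where many genes change. With an untreated library of its own for each compound, an alternative chosen after the data were seen, the correlations were 0.567 and 0.511 at day 1, 0.493 and 0.443 at day 3 and 0.247 and 0.188 at day 5 for the 2 ways of assigning the libraries. The covariances were then 1.87 and 1.75, 1.76 and 1.64, and 0.778 and 0.613.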

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

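Both tests of the genes near 0 at days 21 and 30, and the tests of a wrong label and of a shared culture state for the MAK683 day 5 library, were chosen after the result was seen, as were the use of an untreated library of its own for each compound and all comparisons of the compound difference between days.

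In the bulk stem cell libraries 19 genes stood at 10 CPM or more in every day 9 library and under 1 CPM in every library of days 21 and 30, Sumo2 (186 against 0.223 CPM at day 21) and Sec61g (79.8 against 0.44 CPM) among them. Loss of the transcripts with time, and libraries of days 9 and 14 counted differently from those of days 21 and 30, for example with another annotation, cannot be told apart for these genes. In single cells 14 of the 19 were under 1 CPM already at day 7, but 8 of these were under 1 CPM in day 12 single cells too while at 10 CPM or more in bulk at days 9 and 14, so their absence from the 3' assay says nothing about loss. Of the 4 genes at 20 CPM or more in day 7 single cells (Sumo2, Sec61g, Gm1821 and Nanp, named after their values were seen), 0 were at least 2-fold lower at day 16. In bulk the same 4 were less than 2-fold lower at day 14 than at day 9, so a loss after day 16 would give that result as well. Mir6236 went the other way, at 0 CPM at days 9 and 14 and at 106 and 72.3 CPM at days 21 and 30. TMM factors also split there, at 0.92 to 0.965 for days 9 and 14 and 1.09 to 1.1 for days 21 and 30. A difference of counting could therefore touch other genes in the comparisons of days 21 and 30 with day 9.

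The day 14 libraries stood apart from those of day 9 at 7508 genes. Progression toward days 21 and 30 is argued against as the main source. Across the genes called at day 14 the Spearman correlation of the changes, taken against different day 9 libraries, was -0.182. Where another source dominates, this correlation cannot show whether progression adds a part. Of 536 genes raised late, 93 were called higher at day 14 and 108 lower. A library preparation that counts transcripts more as the 3' single-cell assay does is a candidate source: across 9770 genes the day 14 difference correlated with the single-cell minus bulk difference at 0.494, where days 21 and 30 gave -0.166. A difference between the animals used at each day stays open, untested. Every day 9 library held Xist and no Eif2s3y count, while both day 14 libraries held the Y-linked Eif2s3y and next to no Xist. Sex can thus not be told apart from day in this comparison, nor in that of day 30 with day 9. Genes are also not independent replicates.

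The MAK683 day 5 library lay nearer to the untreated libraries (root mean square log2 difference of 0.968) than the other treated groups did (1.14 to 1.44). A wrong label on untreated cells is argued against: 1710 genes that rose late under UNC1999 had a median log2 change of 1.16 in it, with quartiles of 0 and 2.17. PRC2 inhibition as the source of the day 1 differences from untreated failed the bound set beforehand. Genes called at day 1 of UNC1999 kept -7.06% of their median change in the MAK683 day 5 library, but that is 1 library. The MAK683 library of day 3, not part of that bound, kept 88.5% (0.7 against 0.79 on the log2 scale). It is measured against the same untreated libraries by which the genes were called. At day 1 the changes under both compounds correlated across genes at 0.743, against 0.36 in simulated unchanged groups, and at 0.567 or 0.511 with an untreated library of its own for each compound. All these values are set against untreated cells of day 5, so a difference of day or culture could give them too, and the source stays open. A culture state that the MAK683 day 5 library shares with the untreated libraries, all labelled day 5, may contribute. The correlation across genes that would show it, 0.284, lay between the bounds set, so this stays open.

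The difference between the compounds itself differed between days at 1501 genes for day 3 against day 1 and at 6391 genes for day 5 against day 1, by edgeR's test of the interaction, with 1 MAK683 library per day. The first count was 895 without UNC1999 day 1 replicate 1. For single genes, the UNC1999 minus MAK683 difference of EZH1 changed by -1.41 on the log2 scale from day 1 to day 5, and that of CDKN2A by 0.44 to day 3 and by -0.35 to day 5. From day 1 to day 3 the list medians of this change were 0.47 for CDK inhibitors, 0.3 for cell cycle genes, 0.59 for plasma cell and memory B cell genes, 0.32 for BCL2 family genes, -0.7 for cholesterol synthesis and uptake genes and 0.43 for ATF4 and unfolded-protein response genes. Camera's adjusted p for these lists was 0.0106, 8.82e-11, 0.0355, 0.0127, 7.06e-30 and 2.78e-05, and adjusted p = 0.242, 0.242, 0.256, 0.393, 0.157 and 0.285 with an estimated correlation. From day 1 to day 5 the medians were 0.8 for cell cycle genes, -1.31 for p53 targets, -0.51 for germinal centre genes (-0.6 with bounds), -1.21 for BCL2 family genes, -0.89 for cholesterol genes and -1.02 for ATF4 and unfolded-protein response genes. Their adjusted p was 6.87e-15, 1.85e-06, 1.07e-06, 0.00248, 6.14e-05 and 1.7e-06, and adjusted p = 0.192, 0.175, 0.283, 0.331, 0.304 and 0.283 with an estimated correlation.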

How the results depend on the processing

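Chosen after the data were seen were the comparisons by day, over days 1 and 3 only and between days, those of days 3 and 6 against day 1, the fits without day 14 or without genes near 0, the raised genes under 1 CPM at day 9, and an untreated library of its own for each compound. For the comparisons fixed beforehand, fold changes of named genes were followed under the alternatives fixed beforehand. Of these values, 7668 kept their side of the threshold, 256 no longer passed, 14 came to pass and 0 changed sign. A change of sign was counted only for a gene that passed in either setting, and genes that passed in neither are among the 7668. For the added alternatives, together with the added comparisons of the compounds by day under any alternative, these numbers were 1477, 96, 1 and 21. The cause was not tested for any change given here unless stated.

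Day 21 against day 9 called 1689 genes with the replicate block and 1864 to 2466 with a library left out, 1864 without day 9 replicate 1, and 1944 and 1962 without day 21 replicates 1 and 2. Day 30 against day 9 called 764 with the replicate block and 875 to 1398 with a library left out, 875 without day 9 replicate 1. Without day 14 these comparisons called 2730 and 1290, and without genes near 0 in a pair of days 2955 and 1493. Day 30 against day 21 called 36 without the filter, 299 with DESeq2, 22 with the replicate block, 34 without day 21 replicate 1 and 335 without replicate 2. Replicate numbers were shared between groups, but same-numbered libraries deviated together with correlations of only -0.02 to 0.05 in mouse (6 pairs) and -0.04 to 0.02 in human (12). No pairing by number was thus seen. In groups of 2 libraries the deviations from their mean mirror each other, so the human values repeat between replicates 1 and 2. Such correlations over all genes cannot exclude a pairing. Against untreated cells no paired analysis was possible because the untreated columns carry no number. UNC1999 against MAK683 called 2929 genes over days 1 and 3 only, and at day 1 1922 with only the groups compared and 761 to 840 with a library left out, 761 without UNC1999 day 1 replicate 1. UNC1999 day 3 against day 1 called 3292 to 5389, 3292 without day 1 replicate 2, and the change from day 1 to day 3 called 895 to 1851, 895 without UNC1999 day 1 replicate 1. Groups of 1 library cannot be left out. With an estimated correlation the calls of lists went from 32 to 0 in mouse and from 45 to 1 in human, and with the replicate block those among treated libraries from 7 to 4.

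Over days 1 and 3 only, 21 named genes that passed in either setting changed sign between the compounds. Their log2 differences were 0.1 for EZH1, 0.02 for CDKN2A, 0.15 for HOXB3, 0.31 for PHF1, 0.03 for PHC3, -0.06 for CBX2, 0.11 for CBX7, 0.12 for CDKN1B, -0.03 for MCM5, -0.05 for MCM4, 0.08 for FAS, 0.06 for TP53INP1, 0.68 for BBC3, 0.14 for IFIH1, -0.07 for BST2, 0.35 for GCSAM, -0.04 for FKBP11, 0.13 for HLA-E, 0.02 for HLA-B, 0.05 for BCL2L11 and -0.18 for SDF2L1. Of these, BBC3 (adjusted p = 0.0118) and GCSAM (adjusted p = 0.0275) passed edgeR's test.

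The share of UMIs on raised genes at days 7, 12 and 16 was 0.759%, 1.08% and 0.655% for genes raised at both late days, and 0.037%, 0.0684% and 0.0533% for genes under 1 CPM at day 9. Fewer genes are counted there, which lowers the shares, and the turned direction between days 7 and 16 for the latter has no tested cause. The correlation between the compounds over genes with mean log2 CPM of at least 3 was 0.913 at day 1, 0.873 at day 3 and 0.251 at day 5. With an untreated library of its own for each compound it was 0.567 or 0.511, 0.493 or 0.443, and 0.247 or 0.188, where both compounds no longer share control values and each control is 1 library. Keeping doublets gave the main values, since the caller did not work. Depth limits genes near the floor: in mouse, 3 counts over the day 9 libraries are 0.044 CPM and over the day 30 library 0.099 CPM.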

Other observations

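The tests of shared genes and of regrouped libraries given here were written before their results were seen. In single cells, other gene groups moved at days when no bulk library was taken. At day 12, 9 of 20 immediate-early and heat-shock genes at 20 CPM or more met the size rule as higher than at day 7 and 1 as lower, and their share of UMIs was 0.514% at day 7, 0.904% at day 12 and 0.502% at day 16. Paneth cell markers had 1 of 17 higher and 11 lower at day 12, with shares of 1.23%, 0.316% and 0.912% of UMIs, and cell cycle genes 0 of 36 higher and 7 lower. Stromal and endothelial markers took 0.0103%, 0.0693% and 0.00252% of UMIs, and their 1 member at 20 CPM or more was higher at day 12. At day 16, interferon-response genes had 0 of 10 higher and 7 lower, with shares of 0.0491%, 0.0613% and 0.0155%. CDK inhibitors had 3 of 5 higher and 0 lower. Each day was 1 library, so none of this has a replicate check.

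Under MAK683 at day 5, plasma cell and memory B cell genes had 8 of 20 higher than untreated and 0 lower (9 and 0 adjusted over the list alone, median 0.41, 0.42 with bounds, camera adjusted p = 0.0122, and adjusted p = 0.231 with an estimated correlation), with the costimulatory gene CD80 at 58.1 against 9.89 CPM and the transcription factor gene IRF4 at 7.43 against 1.57 CPM. Immediate-early and heat-shock genes had 6 of 19 higher and 1 lower (median 0.4, camera adjusted p = 0.032, and adjusted p = 0.354 with an estimated correlation), FOS being at 12.2 against 2.74 CPM. Of 16 p53 targets 3 were higher and 1 lower (3 and 3 adjusted over the list alone), with a median of -0.02 and a mean of 0.14 (camera adjusted p = 0.82).

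A hypothesis was that genes PRC2 keeps silent are the same in both kinds of cell, so that genes raised late after Eed deletion would be raised between days 1 and 5 of UNC1999. Among 587 genes of shared symbol under 1 CPM at both starting points, 77 were raised in mouse, 165 in human and 24 in both, an odds ratio of 1.18 (95% interval 0.672 to 2.04, two-sided Fisher's exact test p = 0.586). Over all 10742 genes of shared symbol the odds ratio was 3.09 (2.38 to 4, Fisher's exact test p = 6.36e-16), with 90 raised in both. The near-silent genes entered only if they passed the expression filter in both organisms. This leaves out genes silent throughout and can lower the odds ratio, so the test cannot decide whether the silenced genes are shared.

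For UNC1999 against MAK683 over days 1, 3 and 5, the libraries were regrouped within days in all 27 ways. In a model of compound and day the real grouping called 162 genes, against 5841 in the fit with a mean per compound and day. The highest of the other groupings called 0, so 1 of 27 gave as many genes, the lowest share possible here. Every other grouping mixes the compounds, which widens its spread. With 1 MAK683 library per day, the test cannot tell an effect of the compound from one of single libraries.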
